A study of Mus musculus with 20 samples.

How the data were processed

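Gene expression was measured by RNA sequencing of total RNA (TruSeq Stranded Total RNA kit per the labels) in 20 libraries, 10 groups with 2 replicates each. The submitters' processing notes name the aligner STAR and the genome build mm10, without versions, and do not say how reads were counted. For the 8 libraries of Py2T LT, M1, M2 and M3 the authors gave RPKM, read off from the values: they are not whole, their sums differ between libraries (340168 to 382930), and low genes step by whole-number ratios. RPKM and FPKM cannot be distinguished in these values, and the absolute depth is unknown. For the 12 M3 shRNA libraries the deposited values were CPM, with the same sum of 1000000 in each library. Every CPM value was a whole multiple of the worth of 1 read, within 0.01 reads in 100% of values, so whole reads were recovered, 16086082 to 24977595 per library. A value of 0 in such a library allows up to 3 reads, 0.120 to 0.186 CPM, which covers counting error only. One RPKM file held 7 further columns equal in all rows to the other files of its set, and only its own column was used, with 0 columns left unmapped.

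Samples were grouped by cell line, shRNA and CI994 as the labels give them. The groups, comparisons, 26 gene lists and rule for named genes were fixed before the data were examined. The design planned edgeR on counts, but the files held RPKM and CPM, so limma was used on log2(value / TMM factor + 0.5), with empirical Bayes moderation, a mean trend and robust settings. Genes with at least 1 RPKM or 0.5 CPM in 2 or more libraries were tested, 11717 and 12808 genes. The 8 RPKM libraries formed 1 fit and the 12 CPM libraries another, with group as the only term, and p was adjusted by Benjamini-Hochberg to a threshold of 0.05. Log2 changes and folds are on the scale of value + 0.5, so that changes of genes near 0 are compressed. Standard errors come from the fit, and SD is that between replicates. Replicate numbers were not treated as pairs. The interaction is the knockdown effect with CI994 minus that without it.

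The gene lists were epithelial, mesenchymal, EMT transcription factors, TGF-beta signalling, NuRD subunits, DNA methylation enzymes and readers, histone deacetylases, cyclin-dependent kinase inhibitors, proliferation, neuronal genes, germline genes, interferon-stimulated genes, MHC class I presentation, p53 targets, apoptosis regulators, the integrated stress and unfolded protein response, cholesterol synthesis, glycolysis and hypoxia, extracellular proteases and inhibitors, Wnt targets, immediate early genes, mammary luminal, mammary basal and myoepithelial, haematopoietic and endothelial markers, and ribosomal proteins. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation, beside fry. Of 334 list tests in 15 comparisons 90 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0700 and 34 had an unadjusted p under 0.05. By fry 195 passed, a test of whether a list's genes move on balance one way, which compares them with no other genes.

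Named genes followed this rule. Tet2, Mbd3, Hdac1, Hdac2, Hdac3, Hdac8, Cdh1, Epcam, Vim, Fn1, Cdh2, Zeb1, Snai1 and Cdkn1a could be named in any comparison. So could the 6 largest rises and 6 largest falls with adjusted p under 0.05, both libraries of one group beyond both of the other and a mean of at least 5 CPM (RPKM for the other set) in the higher group, leaving out numbered gene models. From each list up to 2 rises and 2 falls with adjusted p under 0.05 and a mean of at least 1 were allowed, or the member with the smallest p in a list without any. For the mean of the clones all 6 clone libraries had to lie beyond both Py2T LT libraries, and for interactions the adjusted p alone counted.

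Alternatives planned were DESeq2 size factors (RLE), library size only, no filter, the replicate number as a block, only the groups compared, DESeq2, an estimated correlation for lists, and leaving out each library in turn. Alternatives chosen after seeing the data were pseudocounts of 0.1 and 1, and removal of each library's trend along gene GC content, alone and with the block. EdgeR quasi-likelihood was the design's main test. Its use as an alternative, on the recovered reads of the CPM libraries, was also chosen after seeing the data. GC content was available for 94.4% of tested RPKM genes and 95.6% of tested CPM genes. The limma test was also tested on simulated data with 1 spread per gene shared by all groups, 100 genes changed 2-fold and 100 changed 4-fold. It found 53% and 91% of them for shTet2 against shControl, 20% and 74% for its interaction and 93% and 99% for the mean of the clones, with 7 to 14 false calls per comparison. The simulated untreated shControl pair lacked the wider spread and the GC trend of the real pair, so these rates do not cover them. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and Python 3.11.15, with seed 1.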

Results

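RNA sequencing of 20 libraries measured gene expression in the mouse mammary tumour line Py2T, derived from the MMTV-PyMT model, and in mesenchymal cells made from it. There were 10 groups of 2 replicates each, from 2 independent experiments per the extract protocol. Py2T LT cells had been kept in 2 ng/ml TGF-beta 1 for more than 10 days, and M1, M2 and M3 were mesenchymal clones. M3 cells also carried a control shRNA or an shRNA against Tet2 or Mbd3, each without and with 2 µM CI994, an inhibitor of class I histone deacetylases, for 72 hours. Tet2 oxidises 5-methylcytosine, and Mbd3 is a subunit of the NuRD complex, which contains the deacetylases Hdac1 and Hdac2. The series title names the role of these proteins in the plasticity between epithelial and mesenchymal states as its question. The 8 libraries of Py2T LT and the clones were given as RPKM for 19311 genes, and their absolute depth is unknown. Their depth relative to Py2T LT replicate 1 ranged from 0.865 to 1.06. The 12 M3 shRNA libraries were given as CPM for 24454 genes and held 16086082 to 24977595 reads. Levels in RPKM and in CPM were not compared with each other, and floors given for 0 reads cover counting error only.

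Tet2 (gene 214133, GRCm38 chromosome 3, 133463677 to 133545136) had its lowest group means in shTet2, without and with CI994, and Mbd3 (gene 17192, chromosome 10, 80392539 to 80399531) was low in the shMbd3 libraries. Tet2 measured 15.1 and 13.8 CPM in the libraries labelled shControl, 8.41 and 7.97 in shTet2, and 10.9 and 12.4 in shMbd3. With CI994 it measured 8.13 and 11.4 CPM in shControl, 6.30 and 7.42 in shTet2, and 11.8 and 10.4 in shMbd3. Mbd3 measured 22.1 and 27.7 CPM in shMbd3 and 56.9 and 66.3 in shTet2. With CI994, Mbd3 measured 16.6 and 21.9 CPM in shMbd3, 53.6 and 67.7 in shControl, and 82.2 and 86.3 in shTet2. In the untreated shControl group Mbd3 was 66.5 CPM in replicate 2 but 5.40 in the library labelled M3_shControl replicate 1, below both shMbd3 libraries. This gene is at odds with that library's label, but a mislabelled shMbd3 library is argued against across genes. After GC correction the library's difference from its replicate correlated at -0.0127 with the shMbd3 effect measured within CI994. That library also differed from its replicate along gene GC content. The median log2 difference between the replicates fell by 1.77 from the lowest to the highest GC decile, against changes between -0.389 and 0.0137 in the other 5 CPM pairs. Every comparison with untreated shControl uses this library, and it also enters the spread that all 12 CPM libraries share in the fit. The number of genes passing in each is also given without it, but overlaps between comparisons and most counts within gene lists are not. In fits without M3_shControl replicate 2 that library is the only untreated shControl, so calls lost or gained there carry its GC trend.

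**Figure D1:**
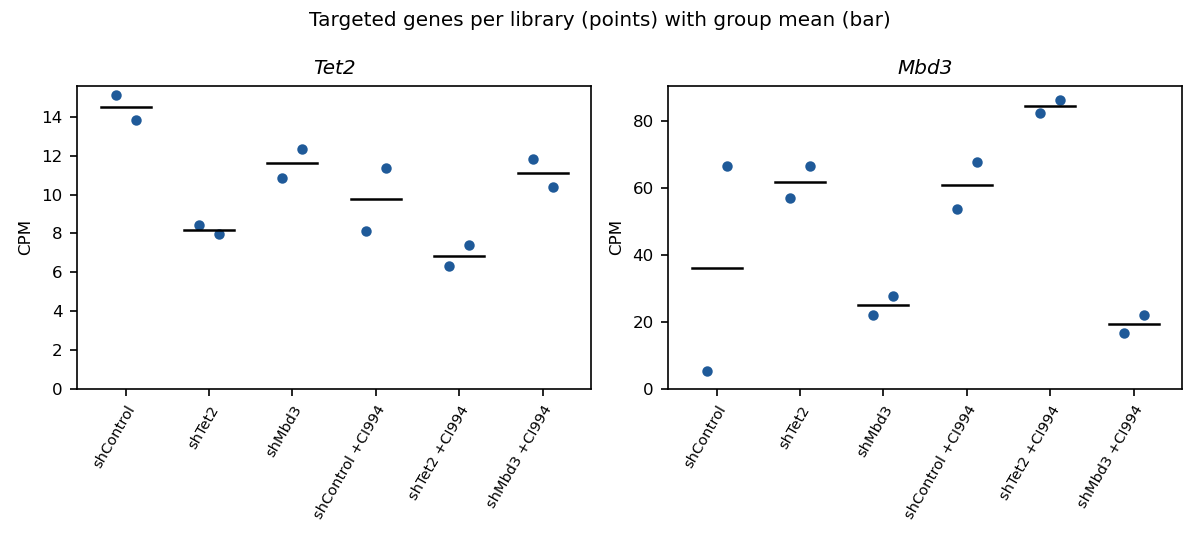
Tet2 and Mbd3 in CPM (vertical axes) in each of the 12 M3 shRNA libraries (points), with the mean of each group (bars). Mbd3 in the library labelled M3_shControl replicate 1, at 5.40 CPM, lies below both shMbd3 libraries.

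**Figure D2:**
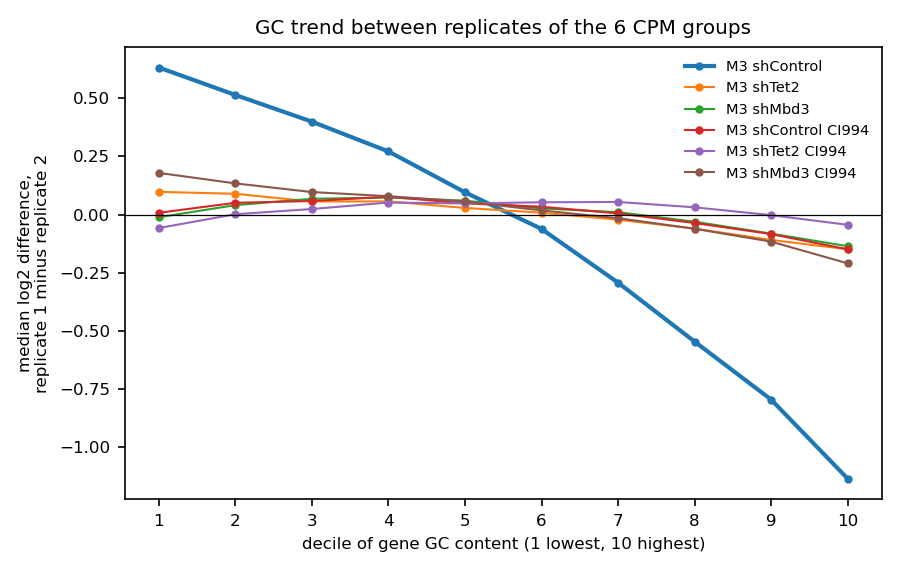
Median log2 difference between replicate 1 and replicate 2 (vertical axis) in each decile of gene GC content (horizontal axis) for the 6 CPM groups (lines). The shControl line goes from 0.63 in the lowest decile to -1.14 in the highest.

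The clones and TGF-beta-treated Py2T cells were compared to ask how stable mesenchymal clones differ from cells held in TGF-beta. The labels do not say whether the clones were kept with or without TGF-beta. The clones expressed more of the mesenchymal cadherin Cdh2, at 46.0 ± 7.7 RPKM (SD, n = 6) against 1.84 ± 0.14 (SD, n = 2) in Py2T LT, but less of the filament protein Vim, at 440 ± 87.2 against 1388 ± 12.3. The matrix protein Fn1 was lower in the clones, at 806 ± 143 against 1515 ± 65.2 RPKM. The epithelial adhesion gene Epcam (gene 17075, chromosome 17, 87635979 to 87651127) was higher, at 17.8 ± 11.3 against 6.71 ± 1.8. E-cadherin, Cdh1 (gene 12550, chromosome 8, 106603350 to 106670247), measured 2.64 ± 2.0 against 1.94 ± 0.54 RPKM, with a log2 difference of 0.13 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.502). Without Py2T LT replicate 2 that difference was -0.10. For the mean of the 3 clones, 7638 of 11717 tested genes passed, 3717 higher and 3921 lower than in Py2T LT. This test does not measure the spread between clones.

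Targets of TGF-beta and regulators of the epithelial to mesenchymal transition (EMT) differed in both directions. The TGF-beta target Ccn2 was 25.0 ± 13 RPKM in the clones (SD, n = 6) and 295 ± 24 in Py2T LT (SD, n = 2), a log2 difference of -3.74 ± 0.49 (SE), whereas the receptor gene Tgfbr3 and the BMP target Id1 were higher by 3.75 ± 0.14 and 2.35 ± 0.14. Of 27 tested genes of TGF-beta signalling, 9 were higher, 13 were lower and 5 did not pass (10 and 14 adjusted over the list alone). Among 19 EMT transcription factors, 7 were higher, 9 lower and 3 did not pass (8 and 9 adjusted over the list alone). Prrx1 and Twist1 were higher by 2.03 ± 0.14 and 1.88 ± 0.10, and Foxc2, Twist2, Zeb1 and Snai1 were lower, with log2 differences of -5.47 ± 0.10, -3.67 ± 0.12, -1.31 ± 0.15 and -1.05 ± 0.16. The mesenchymal list had 5 higher, 11 lower and 3 not passed of 19 (5 and 11 adjusted over the list alone; camera adjusted p = 0.192), with the collagen Col5a1 and the collagen cross-linking enzyme Loxl2 at -4.53 ± 0.11 and -4.00 ± 0.10. The epithelial list had 18 higher, 3 lower and 6 not passed of 27 (18 and 3 adjusted over the list alone). The tight junction gene Cldn6 was higher by 6.62 ± 0.10 and the protease inhibitor Spint1 by 3.53 ± 0.15, while Cldn4 and the junction gene Jup were lower, at -3.79 ± 0.13 and -0.89 ± 0.12. Camera gave adjusted p = 0.00115 for the epithelial list with its preset correlation, and adjusted p = 0.719 with an estimated correlation.

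The largest differences of single genes included the neural progenitor filament Nes (gene 18008, chromosome 3, 87971093 to 87980451) at 0.0579 ± 0.019 RPKM in the clones (SD, n = 6) against 202 ± 23 in Py2T LT (SD, n = 2). The deubiquitinase Uchl1 was 0.0463 ± 0.055 against 94.2 ± 10. The secreted superoxide dismutase Sod3 and the activin subunit Inhbb were higher in the clones, at 85.8 ± 64 and 89.3 ± 15 RPKM against 0.337 ± 0.21 and 0.635 ± 0.36. Tested genes of the integrated stress and unfolded protein response were lower in 18 of 22 cases and higher in 0, with Atf3 and the folate enzyme Mthfd2 both at -2.41 (SE 0.28 and 0.20). Cholesterol synthesis genes were lower in 16 of 22 cases and higher in 1, with Dhcr7 at -1.14 ± 0.10 and Cyp51 at -1.12 ± 0.10. Genes of MHC class I presentation were higher in 9 of 12 cases and lower in 1, with H2-T23 and the peptide transporter Tap2 up by 2.32 ± 0.12 and 2.26 ± 0.13 and the class I gene H2-D1 lower at -0.51 ± 0.10. Adjusted over the list alone these 3 lists gave the same counts. Their camera adjusted p were 0.000840, 0.0127 and 0.00637 with the preset correlation. With an estimated correlation none passed: adjusted p = 0.719 for the stress list, adjusted p = 0.725 for cholesterol synthesis and adjusted p = 0.719 for MHC class I. Without Py2T LT replicate 2 the cholesterol call was lost as well (adjusted p = 0.0727).

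Both targets of the later knockdowns were expressed in the clones. Mbd3 was lower than in Py2T LT, at 95.2 ± 16 against 132 ± 4.7 RPKM, a log2 difference of -0.52 ± 0.11 (SE). Tet2 was 2.31 ± 0.56 against 1.47 ± 0.068 RPKM (adjusted p = 0.0447), a call lost without either Py2T LT library, either M2 library or either M3 library, with differences from 0.42 to 0.50, and also without a filter (0.46, adjusted p = 0.0732) and at a pseudocount of 0.1 (0.54, adjusted p = 0.0522). The deacetylase genes Hdac1 and Hdac3 were higher by 1.24 ± 0.10 and 0.38 ± 0.08, Hdac2 was lower at -0.49 ± 0.10, and Hdac8 differed by 0.04 ± 0.10 (adjusted p = 0.762; -0.00 without Py2T LT replicate 1). In the other lists the numbers higher, lower and not passed were 4, 6 and 4 for NuRD subunits, 6, 5 and 3 for DNA methylation enzymes and readers, and 4, 3 and 3 for histone deacetylases. They were 14, 11 and 10 for proliferation, 2, 4 and 0 for neuronal genes, and 8, 3 and 3 for interferon-stimulated genes. They were 9, 6 and 4 for p53 targets (10 and 6 adjusted over the list alone), 9, 6 and 7 for apoptosis regulators, and 11, 10 and 2 for glycolysis and hypoxia. They were 7, 9 and 3 for extracellular proteases and inhibitors, where Mmp9 was lower at -5.41 ± 0.15, and 3, 6 and 1 for Wnt targets, where Lef1 was lower at -5.39 ± 0.10. They were 5, 7 and 6 for immediate early genes (5 and 8 adjusted over the list alone), 3, 3 and 1 for mammary luminal markers, 1, 2 and 2 for basal markers, and 8, 2 and 25 for ribosomal proteins (7 and 2 adjusted over the list alone). For the remaining lists of this paragraph the counts adjusted over the list alone were the same, and none of these lists passed camera. Haematopoietic and endothelial markers had 2 tested genes each, with 1 haematopoietic gene higher and 1 endothelial gene in each direction, and no germline gene was tested.

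The cyclin-dependent kinase inhibitors had 1 gene higher, 4 lower and 2 not passed of 7 (1 and 4 adjusted over the list alone; camera adjusted p = 0.192), and the lower genes included a neighbouring pair. Cdkn2a (gene 12578, chromosome 4, 89274473 to 89294619) was 59.5 ± 8.5 RPKM in Py2T LT (SD, n = 2) and at most 0.0533 in any of the 6 clone libraries. Cdkn2b, beside it, was 46.5 ± 2.0 in Py2T LT and at most 0.0483 in the clones. Both had 0 reads in all 12 M3 shRNA libraries, which allows up to 0.120 to 0.186 CPM per library. Further along chromosome 4, Dmrta1 and Tusc1, chosen after their values were seen, were also lower in the clones. They were 2.32 ± 0.16 and 4.15 ± 0.86 RPKM in Py2T LT and at most 0.0461 and 0 in any clone library. The gene model Gm12669 between them did not pass (limma adjusted p = 0.770). Cdkn1a, the p21 gene, differed by 0.17 ± 0.10 (SE; adjusted p = 0.168). A second group of neighbours was lower together: Mdm2 (gene 17246, chromosome 10, 117688875 to 117710758), which encodes the ligase that degrades p53, was 47.5 ± 6.2 RPKM in the clones against 667 ± 4.2. The 8 consecutive tested genes from Cpm to Dyrk2 (117629500 to 118889245), chosen after their values were seen, had log2 differences from -5.66 to -2.82.

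**Figure D3:**
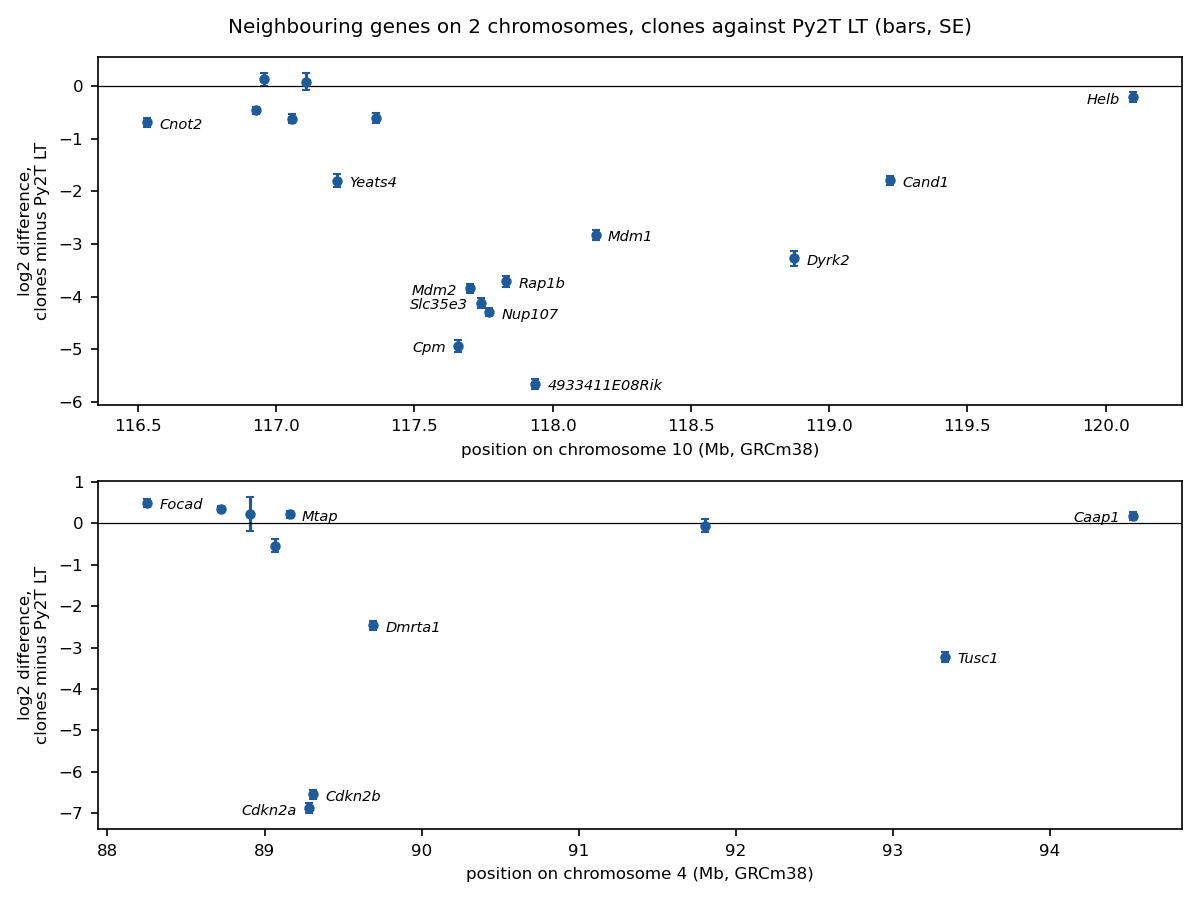
Log2 difference between the mean of the clones and Py2T LT (vertical axis, bars SE) for tested genes by position in Mb on chromosomes 10 and 4 (horizontal axes). The 8 genes from Cpm to Dyrk2 lie at or below -2.82, and Cdkn2a and Cdkn2b lie below -6.5.

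Each clone differed from Py2T LT in a similar number of genes, and the clones also differed from each other. M1 had 7152 genes past the threshold (3535 higher, 3617 lower), M2 6732 (3243 and 3489) and M3 6979 (3383 and 3596). Cldn6 separated the clones, at 175 ± 3.7 RPKM in M1, 11.6 ± 0.25 in M2 and 235 ± 18 in M3 (SD, n = 2 each; adjusted p = 1.01e-06 among clones). The neuronal gene Brinp3 was 75.3 ± 16 RPKM in M2 and 0.885 and 1.38 on average in M1 and M3 (adjusted p = 0.00103), and Sod3 was 167 ± 1.6 in M2, 58.6 ± 13 in M1 and 31.8 ± 4.3 in M3 (adjusted p = 0.000273). Against Py2T LT, the transcription factor Foxf1 was higher by 6.06 ± 0.11 (SE) in M2 and Sytl2 by 6.39 ± 0.12 in M3. Serpinb2 was lower by -7.09 ± 0.14 in M1. Among the clones 3009 genes differed, with 2688 between M1 and M2, 2359 between M2 and M3, and 580 between M1 and M3. The count of 3009 was 1017 and 1082 without M2 replicate 2 or 1, 1988 without M3 replicate 1, and 5981 without M1 replicate 2. Camera called the epithelial list in M1, M2 and M3 (adjusted p = 0.0166, 0.000437 and 0.000538), and the stress list in the same order (adjusted p = 0.00214, 0.00182 and 0.000487). The epithelial call in M1 was lost without a filter (adjusted p = 0.149). The MHC class I list was called in M1 and M3 (adjusted p = 0.00214 and 0.00364) but not in M2, with 5 higher, 1 lower and 6 not passed of 12 (adjusted p = 0.0902). Cholesterol synthesis was likewise called lower in M1 and M3 (adjusted p = 0.0107 and 0.000596) but not in M2, with 2 higher, 7 lower and 13 not passed of 22 (adjusted p = 0.535). Camera gave adjusted p = 0.298, 0.0250 and 0.222 for lower values of the mesenchymal list in M1, M2 and M3, and the M2 call was lost with only the groups compared (adjusted p = 0.0588). Wnt targets were called lower in M2 (adjusted p = 0.0250), a call lost without a filter (adjusted p = 0.254) or with only the groups compared (adjusted p = 0.0672). Differences between the clones were not tested for any list. With an estimated correlation every list in M1 had adjusted p = 0.746 or more, in M2 adjusted p = 0.720 or more and in M3 adjusted p = 0.659 or more.

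Knockdown of Tet2 in M3 was compared with shControl to ask what Tet2 maintains in mesenchymal cells, and epithelial genes rose while several mesenchymal regulators fell. Cdh1 rose from 16.3 and 25.7 CPM in the libraries labelled shControl to 205 ± 3.2 in shTet2 (SD, n = 2 each), a log2 change of 3.32 ± 0.16 (SE; adjusted p = 2.42e-06). Epcam rose by 2.26 ± 0.11, the splicing factor Esrp1, which controls epithelial isoforms, by 3.98 ± 0.13, and the membrane protease St14 by 3.41 ± 0.28. Of 34 tested epithelial genes, 28 rose, 0 fell and 6 did not pass (32 and 1 adjusted over the list alone). Vim fell from 1493 ± 44.7 to 336 ± 20.8 CPM, by a log2 change of -2.12 ± 0.10, and Zeb1, a repressor of Cdh1, from 55.0 ± 4.0 to 17.8 ± 0.77. Of 18 EMT transcription factors 1 rose, 9 fell and 8 did not pass (2 and 10 adjusted over the list alone), with Prrx1 at -3.28 ± 0.18 and Tbx3 at -2.63 ± 0.23. The mesenchymal list moved both ways, with 3 higher, 7 lower and 14 not passed of 24 (4 and 8 adjusted over the list alone; camera adjusted p = 0.395). In it the matrix gene Tnc rose by 3.55 ± 0.11 and the collagen Col6a1 fell by 3.27 ± 0.43 on the log2 scale, while Fn1 was 2279 ± 65.8 CPM against 3229 ± 1232 (adjusted p = 0.143). Fn1 passed without the library labelled M3_shControl replicate 1 (-0.76) and with the GC trend removed (-0.60). Camera gave adjusted p = 4.33e-20 for the epithelial list and 0.00120 for the EMT factors with the preset correlation, and adjusted p = 0.159 for both with an estimated correlation. With the GC trend removed the epithelial list passed with an estimated correlation (adjusted p = 0.0167).

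The largest changes with Tet2 knockdown were falls of the phospholipase gene Plce1, from 120 ± 6.6 to 1.07 ± 0.38 CPM (SD, n = 2 each), and of the chondroitin sulfotransferase gene Chst11, from 71.3 ± 1.8 to 0.239 ± 0.20. B4galnt3, Adam22 and the receptor Epha1 rose by 4.30 ± 0.21, 4.33 ± 0.28 and 3.40 ± 0.13 (log2, SE). Genes of glycolysis and hypoxia rose in 19 of 24 cases and fell in 1 (21 and 1 adjusted over the list alone), including the carbonic anhydrase Car9 by 2.24 ± 0.30 and Pfkp by 1.83 ± 0.15, with Egln3 down by -0.96 ± 0.15. Cholesterol synthesis genes rose in 16 of 22 cases and fell in 1 (19 and 1 adjusted over the list alone), with Hmgcs1 up by 1.16 ± 0.16. In the stress list 12 of 22 rose and 0 fell (13 and 0 adjusted over the list alone), with Atf3 up by 2.51 ± 0.16 and Sesn2 by 1.52 ± 0.26. Of 19 p53 targets 8 rose and 0 fell (9 and 0 adjusted over the list alone), with Btg2 at 1.58 ± 0.24. In TGF-beta signalling 7 rose, 6 fell and 16 did not pass of 29 (9 and 6 adjusted over the list alone; camera adjusted p = 0.816), with the activin subunit Inhba up by 1.72 ± 0.16 and Tgfbr3 down by -2.42 ± 0.16. The growth factor binding protein gene Igfbp3 changed by -2.68 ± 0.26. Camera adjusted p were 3.95e-09, 2.09e-08, 0.000178 and 0.00271 for glycolysis and hypoxia, cholesterol, stress and p53. With an estimated correlation they were adjusted p = 0.159, adjusted p = 0.176, adjusted p = 0.172 and adjusted p = 0.172, and the p53 call was also lost without M3_shControl replicate 2 (adjusted p = 0.117). With only the groups compared the calls of Egln3 (adjusted p = 0.132), Hmgcs1 (adjusted p = 0.0656), Sesn2 (adjusted p = 0.163) and Btg2 (adjusted p = 0.116) were lost. Camera also called immediate early genes (adjusted p = 0.000373) and ribosomal proteins (adjusted p = 2.21e-07) higher, and Wnt targets (adjusted p = 0.0439) and basal markers (adjusted p = 0.0476) lower. These calls did not hold with an estimated correlation (adjusted p = 0.172 or more), and the calls of Wnt targets and basal markers were also lost without 1 library or in another setting (adjusted p = 0.0506 to 0.154 in settings that kept both replicates). The single libraries were the one labelled M3_shControl replicate 1, M3_shControl replicate 2 and shTet2 replicate 1. The call of immediate early genes was lost with the block and the GC trend removed (adjusted p = 0.0506). Their counts were 7 higher and 1 lower of 18 for immediate early genes (9 and 1 adjusted over the list alone), 2 higher and 5 lower of 12 for Wnt targets (2 and 5 adjusted over the list alone), 1 higher and 4 lower of 7 for basal markers (2 and 4 adjusted over the list alone) and 14 higher and 0 lower of 35 for ribosomal proteins (23 and 0 adjusted over the list alone).

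In all, 2975 of 12808 tested genes passed for shTet2 against shControl, 1340 higher and 1635 lower. Tet2 itself changed by -0.76 ± 0.18 (SE; adjusted p = 0.0176), a call lost without either shTet2 library (-0.80 and -0.72) or with only these groups in the fit (-0.75). Mbd3 was 61.6 ± 6.7 CPM in shTet2 against 36.0 ± 43 in shControl (SD, n = 2 each; adjusted p = 0.162), with a log2 difference of 1.67, which was -0.02 without the library labelled M3_shControl replicate 1 and passed at 3.37 without replicate 2. Leaving out the library labelled M3_shControl replicate 1 gave 4201 genes (2097 higher, 2104 lower), and in that fit 29 epithelial genes rose and 0 fell. The GC trend of that library is part of the main values: with the trend removed from every library 4875 genes passed, and 31 epithelial genes rose and 1 fell. The count was 8089 without M3_shControl replicate 2, 1504 and 1338 without shTet2 replicate 1 or 2, and 330 with only these groups in the fit.

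Knockdown of Mbd3 was compared with shControl to ask what the NuRD subunit maintains, and epithelial genes were again higher and Vim and Zeb1 lower. Cdh1 was 186 ± 23 CPM in shMbd3 against 16.3 and 25.7 in shControl (SD, n = 2 each), a log2 change of 3.09 ± 0.16 (SE; adjusted p = 5.43e-06). Epcam, Esrp1 and Cldn4 rose by 2.54 ± 0.11, 3.48 ± 0.13 and 3.65 ± 0.40. Of 34 epithelial genes 25 rose, 0 fell and 9 did not pass (26 and 0 adjusted over the list alone). Vim fell to 402 ± 9.4 from 1493 ± 44.7 CPM, and Zeb1 to 20.2 ± 1.2 from 55.0 ± 4.0. The mesenchymal list had 9 higher, 10 lower and 5 not passed of 24 (10 and 10 adjusted over the list alone; camera adjusted p = 0.926, and adjusted p = 0.706 in the other direction without the library labelled M3_shControl replicate 1), with Tnc higher and Col6a1 changed by -4.13 ± 0.43. Of 18 EMT transcription factors 1 rose, 8 fell and 9 did not pass (1 and 9 adjusted over the list alone): the chromatin factor Hmga2 rose by 0.60 ± 0.12 and Prrx1 changed by -1.76 ± 0.18. Camera gave adjusted p = 6.48e-16 for the epithelial list and 0.0468 for the EMT factors, and adjusted p = 0.535 for both with an estimated correlation. With the GC trend removed the epithelial list passed with an estimated correlation too (adjusted p = 0.0362). The EMT factor call was also lost without M3_shControl replicate 2 or shMbd3 replicate 1, with the GC trend removed (adjusted p = 0.0840) and at a pseudocount of 0.1 (adjusted p = 0.0554). With the replicate number as a block it was lost too (adjusted p = 0.0897, and 0.149 with the GC trend removed as well). With only the groups compared the calls of Zeb1 (-1.47, adjusted p = 0.0503), Cldn4 (adjusted p = 0.0517) and Hmga2 (adjusted p = 0.181) were lost.

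Among the genes with the largest changes, the receptor tyrosine kinase Ret rose from 2.03 ± 0.30 to 64.9 ± 0.65 CPM (SD, n = 2 each), Gpa33 from 2.15 ± 1.2 to 41.2 ± 13, and the natriuretic peptide receptor Npr3 by 3.63 ± 0.29 (log2, SE). Plce1 fell from 120 ± 6.6 to 0.751 ± 0.18, Gpnmb from 144 ± 52 to 3.41 ± 1.2, the interleukin receptor Il1rl1 from 117 ± 2.5 to 3.50 ± 0.47 and the integrin Itga8 from 33.2 ± 4.2 to 0.673 ± 0.18. Genes of MHC class I presentation rose in 9 of 13 cases and fell in 0 (10 and 2 adjusted over the list alone), with the immunoproteasome gene Psmb8 at 1.60 ± 0.35 (log2, SE), a call lost without shMbd3 replicate 1 (1.44) and with only the groups compared (adjusted p = 0.105). Camera gave adjusted p = 0.00503 for this list, and adjusted p = 0.688 with an estimated correlation. Camera also called the stress list (adjusted p = 0.0277), cholesterol synthesis (adjusted p = 0.0468), glycolysis and hypoxia (adjusted p = 0.0468) and ribosomal proteins (adjusted p = 0.0158) higher. Without the library labelled M3_shControl replicate 1 the calls of cholesterol synthesis, glycolysis and hypoxia, and ribosomal proteins were lost. No call of the 4 held with an estimated correlation (adjusted p = 0.688), and each was also lost without 1 library or in another setting (adjusted p = 0.0509 to 0.148 in settings that kept both replicates). Their counts were 10 higher and 0 lower of 22 for the stress list (10 and 0 adjusted over the list alone), 6 higher and 1 lower of 22 for cholesterol synthesis (8 and 1 adjusted over the list alone), 7 higher and 2 lower of 24 for glycolysis and hypoxia (8 and 2 adjusted over the list alone) and 3 higher and 0 lower of 35 for ribosomal proteins (0 and 0 adjusted over the list alone). In TGF-beta signalling 8 rose, 6 fell and 15 did not pass of 29 (8 and 6 adjusted over the list alone; camera adjusted p = 0.824), with Ccn2 up by 1.69 ± 0.16 and Tgfbr3 at -1.70 ± 0.16. Of 22 proteases and inhibitors 5 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.419), with the gelatinase Mmp9 up by 3.14 ± 0.16 and the stromelysin Mmp3 at -2.83 ± 0.25. Basal markers moved both ways, 2 up and 4 down of 7 (2 and 4 adjusted over the list alone; camera adjusted p = 0.351), with the keratin Krt14 at 2.95 ± 0.41 and the kinase Mylk at -3.19 ± 0.31. Cdkn1a and Atf3 rose by 0.94 ± 0.13 and 2.74 ± 0.16. The calls of Krt14 (adjusted p = 0.0732) and Cdkn1a (adjusted p = 0.0775) were lost with only the groups compared. In all, 4117 genes passed, 1997 higher and 2120 lower.

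Mbd3 itself did not pass against untreated shControl, at 24.9 ± 3.9 against 36.0 ± 43 CPM (SD, n = 2 each; log2 difference 0.29 ± 0.81 SE, adjusted p = 0.794). Its sign depended on the library labelled M3_shControl replicate 1, without which Mbd3 fell by 1.41 (adjusted p = 0.000175), and without M3_shControl replicate 2 it was higher by 1.99. Tet2 was 11.6 ± 1.1 against 14.5 ± 0.92 CPM (adjusted p = 0.149), and passed without M3_shControl replicate 2 (-0.49). Leaving out the library labelled M3_shControl replicate 1 gave 4393 genes (2199 higher, 2194 lower), with 25 epithelial genes higher and 1 lower. The count was 8696 without M3_shControl replicate 2, 1560 and 1753 without shMbd3 replicate 1 or 2, and 306 with only these groups in the fit.

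The genes that differed from shControl overlapped between the Tet2 and Mbd3 knockdowns. Against untreated shControl, 699 genes were higher in both, 865 lower in both and 125 changed in opposite directions, and independent lists would share 209 and 271. The changes correlated across genes at r = 0.677, but both comparisons share the shControl libraries, and simulated data with no knockdown effect and the same shared control gave r = 0.829 with 6.49 higher and 7.12 lower genes shared on average over 100 draws. The covariance was 0.353, against 0.127 in that simulation. Within CI994 the library labelled M3_shControl replicate 1 enters the shared spread but not the group means. There 344 genes were higher and 490 lower in both knockdowns and 102 were opposite. Independent lists would share 67.0 and 129 there, and the covariance of 0.202 compared with 0.0129 simulated. Genes are not independent replicates, so no p is attached to these correlations. The simulation covers noise in the shared libraries only. A difference of the shControl cells from both knockdown lines was not tested.

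CI994 was applied to M3 shControl cells to ask how class I deacetylase inhibition changes expression. The protease inhibitor Slpi rose from 4.83 ± 1.7 to 77.5 ± 1.6 CPM (SD, n = 2 each), the acute phase gene Lbp from 1.32 ± 0.37 to 25.4 ± 1.5, the chemokine Ccl7 from 2.05 ± 0.60 to 35.9 ± 0.94 and the collagenase Mmp13 from 37.6 ± 3.8 to 525 ± 138. The EMT factor Hmga2 fell from 1273 ± 120 to 272 ± 25.8 CPM and Itga8 from 33.2 ± 4.2 to 2.57 ± 0.13. Igfbp3, the cannabinoid receptor Cnr1 and Sema5a changed by -3.24 ± 0.26, -2.66 ± 0.35 and -2.54 ± 0.22 (log2, SE). Epithelial genes rose in 20 of 34 cases and fell in 0 (22 and 0 adjusted over the list alone), and Cdh1 changed from 16.3 and 25.7 to 35.6 ± 1.4 CPM, by 0.75 ± 0.16 (adjusted p = 0.00975). The Cdh1 call was lost without either CI994 library (0.78 and 0.75). Of 18 EMT transcription factors 2 rose, 9 fell and 7 did not pass (2 and 9 adjusted over the list alone), with Prrx1 at -1.85 ± 0.18. Zeb1 was 52.7 ± 2.5 against 55.0 ± 4.0 CPM (adjusted p = 0.577), a log2 difference of -0.09 that was 0.04 without the library labelled M3_shControl replicate 1, and Vim was 1675 ± 22.6 against 1493 ± 44.7 (adjusted p = 0.313). With the GC trend removed Vim passed upward with CI994 (0.32, adjusted p = 0.0459). Camera adjusted p were 9.56e-07 for the epithelial list and 0.00889 for the EMT factors, with adjusted p = 0.437 for both with an estimated correlation. The EMT factor call was also lost without M3_shControl replicate 2, where the library labelled M3_shControl replicate 1 is the only untreated shControl.

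With CI994 in shControl cells the mesenchymal list had 8 higher, 4 lower and 12 not passed of 24 (9 and 5 adjusted over the list alone; camera adjusted p = 0.199), and Fn1 rose by 1.03 ± 0.19 (log2, SE; n = 2 each). The TGF-beta target Ccn2 rose from 50.5 ± 5.6 to 147 ± 0.98 CPM (SD), and the cell cycle inhibitors Cdkn1a and Cdkn2d by 0.74 ± 0.13 and 1.24 ± 0.14. Genes of MHC class I presentation rose in 8 of 13 cases and fell in 1 (9 and 1 adjusted over the list alone): the class I transactivator Nlrc5 rose by 2.81 ± 0.18 and H2-D1 by 2.56 ± 0.19, and the peptidase Erap1 changed by -1.60 ± 0.19. Glycolysis and hypoxia genes rose in 13 of 24 cases and fell in 1 (14 and 1 adjusted over the list alone), with Pfkp and Car9 up by 2.64 ± 0.15 and 1.98 ± 0.30. Proteases and inhibitors rose in 10 of 22 cases and fell in 2 (10 and 2 adjusted over the list alone), with the plasminogen activator Plat up by 1.96 ± 0.16. The basal keratin Krt14 rose by 3.50 ± 0.41 and the antiviral gene Bst2 by 1.46 ± 0.18. Camera adjusted p were 0.00145, 0.00145 and 0.00401 for MHC class I, glycolysis and hypoxia, and proteases. With an estimated correlation each was adjusted p = 0.437, and the protease call was also lost without M3_shControl replicate 2 (adjusted p = 0.0824). Camera also called ribosomal proteins (adjusted p = 0.0237) higher. This call did not hold with an estimated correlation (adjusted p = 0.654). It was also lost without the library labelled M3_shControl replicate 1 or without shControl_CI994 replicate 1. In all, 4286 genes passed, 2306 higher and 1980 lower, and among changes of at least 2-fold 1040 were higher and 324 lower. Without the library labelled M3_shControl replicate 1 the count was 3803 (2066 and 1737), and without replicate 2 it was 8973. It was 1118 and 1395 without CI994 replicate 1 or 2, and limma with only these groups in the fit called 0 genes, 2625 at an unadjusted p under 0.05, so every gene call given for CI994 in shControl cells was lost there. The Cdkn1a call was lost with the GC trend removed (0.34).

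CI994 was also given to the knockdown cells. Of the genes it changed in shControl cells, 984 were also higher and 996 also lower with CI994 in shTet2 cells, against 286 and 233 for independent lists. In shTet2 cells the sodium channel gene Scn3a rose from 0.0236 ± 0.033 to 18.3 ± 4.4 CPM (SD, n = 2 each), Sema4f from 0.341 ± 0.081 to 15.5 ± 3.8, the complement gene C1s1 from 2.53 ± 0.97 to 51.3 ± 16 and Krt14 from 4.64 ± 0.62 to 62.0 ± 13. Plat, Nlrc5 and Bst2 rose by 2.92 ± 0.16, 2.92 ± 0.18 and 2.26 ± 0.18 (log2, SE), and Fn1 by 1.63 ± 0.19. Hmga2, Cnr1, Sema5a and Erap1 changed by -1.88 ± 0.12, -2.94 ± 0.35, -2.63 ± 0.22 and -1.17 ± 0.19. Interferon-stimulated genes rose in 12 of 24 cases and fell in 0 (13 and 0 adjusted over the list alone), and cholesterol synthesis genes rose in 0 of 22 and fell in 9 (0 and 9 adjusted over the list alone), with Idi1 at -1.20 ± 0.15. Camera adjusted p were 1.96e-05 and 0.00313 for these lists, and adjusted p = 0.146 and adjusted p = 0.576 with an estimated correlation. Camera also called the epithelial list (adjusted p = 0.0330), the mesenchymal list (adjusted p = 0.0251), neuronal genes (adjusted p = 0.00313), MHC class I presentation (adjusted p = 1.96e-05) and p53 targets (adjusted p = 0.0330) higher, and EMT transcription factors (adjusted p = 0.0330) and proliferation (adjusted p = 0.0232) lower. These calls did not hold with an estimated correlation (adjusted p = 0.175 or more), and the calls of the epithelial list, the mesenchymal list, EMT transcription factors, neuronal genes and p53 targets were also lost without 1 library or in another setting (adjusted p = 0.0561 to 0.408). Cdh1, already 205 ± 3.2 CPM in shTet2, was 320 ± 1.1 with CI994 (adjusted p = 0.0310), a call lost without any single one of these 4 libraries (0.56 to 0.58). Of 12808 genes 3096 passed, 1589 higher and 1507 lower, and the count was 1157 and 1071 without shTet2 replicate 1 or 2, 904 and 1362 without their CI994 counterparts, and 7350 with only these groups in the fit.

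In shMbd3 cells the invariant chain gene Cd74 rose with CI994 from 0.502 ± 0.24 to 15.4 ± 1.9 CPM (SD, n = 2 each), Ccl9 from 3.53 ± 0.44 to 62.9 ± 7.7, Ccl7 from 0.365 ± 0.074 to 10.7 ± 2.3 and Ccl2 from 2.76 ± 0.0080 to 35.0 ± 8.1. Mmp13 and Plat rose by 3.04 ± 0.22 and 2.50 ± 0.16 (log2, SE), and Rcbtb2 and Hmga2 changed by -1.97 ± 0.18 and -1.29 ± 0.12. Genes of MHC class I presentation rose in 9 of 13 cases and fell in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 2.20e-05, and adjusted p = 0.196 with an estimated correlation), with Nlrc5 and H2-D1 up by 1.83 ± 0.18 and 1.48 ± 0.19. Mesenchymal genes rose in 8 of 24 cases and fell in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00595, and adjusted p = 0.196 with an estimated correlation). Camera also called the epithelial list (adjusted p = 0.0152), neuronal genes (adjusted p = 0.00593), interferon-stimulated genes (adjusted p = 0.0183), p53 targets (adjusted p = 0.00892) and proteases and inhibitors (adjusted p = 0.00892) higher, and the stress list (adjusted p = 0.0166) and cholesterol synthesis (adjusted p = 0.00391) lower. No such call held with an estimated correlation (adjusted p = 0.196 or more), and the calls of the epithelial list, neuronal genes and the stress list were also lost without 1 library or in another setting (adjusted p = 0.0504 to 0.0978). Cdh1 was 207 ± 7.7 CPM with CI994 and 186 ± 23 without (adjusted p = 0.591). In all, 1608 genes passed, 951 higher and 657 lower, with 448 and 500 without shMbd3 replicate 1 or 2, 450 and 568 without their CI994 counterparts, and 4637 with only these groups in the fit. Between the disjoint comparisons of CI994 in shTet2 and in shMbd3 cells, 748 genes were higher in both, 464 lower in both and 0 opposite, against 118 and 77.3 for independent lists.

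Within CI994-treated cells the knockdowns were compared with shControl_CI994, without any untreated library. Cdh1 was 320 ± 1.1 CPM in shTet2_CI994 and 207 ± 7.7 in shMbd3_CI994 against 35.6 ± 1.4 in shControl_CI994 (SD, n = 2 each), with log2 changes of 3.14 ± 0.16 and 2.48 ± 0.16 (SE). Epcam was higher by 1.92 ± 0.11 and 1.95 ± 0.11, the epithelial GTPase Rab25 by 3.19 ± 0.25 and 3.64 ± 0.25, and Tnc by 3.76 ± 0.11 and 3.86 ± 0.11. Vim changed by -2.01 ± 0.10 and -1.74 ± 0.10 and Zeb1 by -1.76 ± 0.13 and -1.38 ± 0.13. Of 34 epithelial genes 25 were higher and 0 lower with shTet2 (27 and 0 adjusted over the list alone; camera adjusted p = 2.62e-18), and 23 were higher and 0 lower with shMbd3 (25 and 0 adjusted over the list alone; camera adjusted p = 5.17e-14). These were adjusted p = 0.153 and adjusted p = 0.539 with an estimated correlation. Plce1 was lower in both, at 1.11 ± 0.048 and 0.741 ± 0.081 against 84.7 ± 5.8 CPM. Tet2 was 6.86 ± 0.80 in shTet2_CI994 against 9.75 ± 2.3 CPM (adjusted p = 0.125). Mbd3 was 19.2 ± 3.8 in shMbd3_CI994 against 60.7 ± 10 CPM, a log2 difference of -1.67 ± 0.81 (adjusted p = 0.196) that passed with the GC trend removed (-1.97) and with only these groups in the fit (-1.67). The standard error of 0.81 includes the spread of Mbd3 in the untreated shControl pair.

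Each knockdown had further large changes within CI994, and the difference between the knockdowns was not tested. With shTet2, Cdh2 was higher by 1.02 ± 0.09 (log2, SE; n = 2 each) and B4galnt3 by 4.48 ± 0.21, while the BMP antagonist Grem1 was 0.504 ± 0.24 against 50.8 ± 19 CPM and the cytokine receptor Csf2rb 0.0211 ± 0.030 against 28.9 ± 6.1. Proliferation genes were lower in 7 of 35 cases and higher in 0 (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.00842, and adjusted p = 0.153 with an estimated correlation), with Top2a at -1.07 ± 0.18. Camera also called p53 targets (adjusted p = 0.000447), the stress list (adjusted p = 0.00747), cholesterol synthesis (adjusted p = 0.00747) and immediate early genes (adjusted p = 0.0117) higher, and EMT transcription factors (adjusted p = 0.0294) and Wnt targets (adjusted p = 0.0304) lower. None of these passed with an estimated correlation (adjusted p = 0.153 or more), and the calls of EMT transcription factors, Wnt targets and immediate early genes were also lost without 1 library or in another setting (adjusted p = 0.0647 to 0.107 in settings that kept both replicates). The mesenchymal list had 2 higher and 6 lower of 24 (8 and 7 adjusted over the list alone; camera adjusted p = 0.925, with the direction turned without shControl_CI994 replicate 1, adjusted p = 0.865, or shTet2_CI994 replicate 1, adjusted p = 0.885), with the receptor Pdgfrb at -2.91 ± 0.39. With shMbd3, Ret was 162 ± 9.0 against 7.34 ± 2.1 CPM and Gpa33 66.7 ± 13 against 2.12 ± 0.057, while Gpnmb was 1.03 ± 0.57 against 44.7 ± 13. Hmga2 and Mmp9 were higher by 1.57 ± 0.12 and 3.61 ± 0.16, Mmp3 and Mmp13 lower at -3.23 ± 0.25 and -2.16 ± 0.22, and Psmb8 higher by 1.98 ± 0.35. Genes of MHC class I presentation were higher in 4 of 13 cases and lower in 0 (4 and 0 adjusted over the list alone; camera adjusted p = 0.00156, and adjusted p = 0.539 with an estimated correlation). For shTet2_CI994, 2022 genes passed (840 higher, 1182 lower), with 984 to 1060 when any one of the 4 libraries was left out and 5230 with only these groups in the fit. For shMbd3_CI994, 2416 passed (1022 and 1394), with 1260 to 1306 when any one was left out and 4708 with only these groups in the fit.

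**Figure D4:**
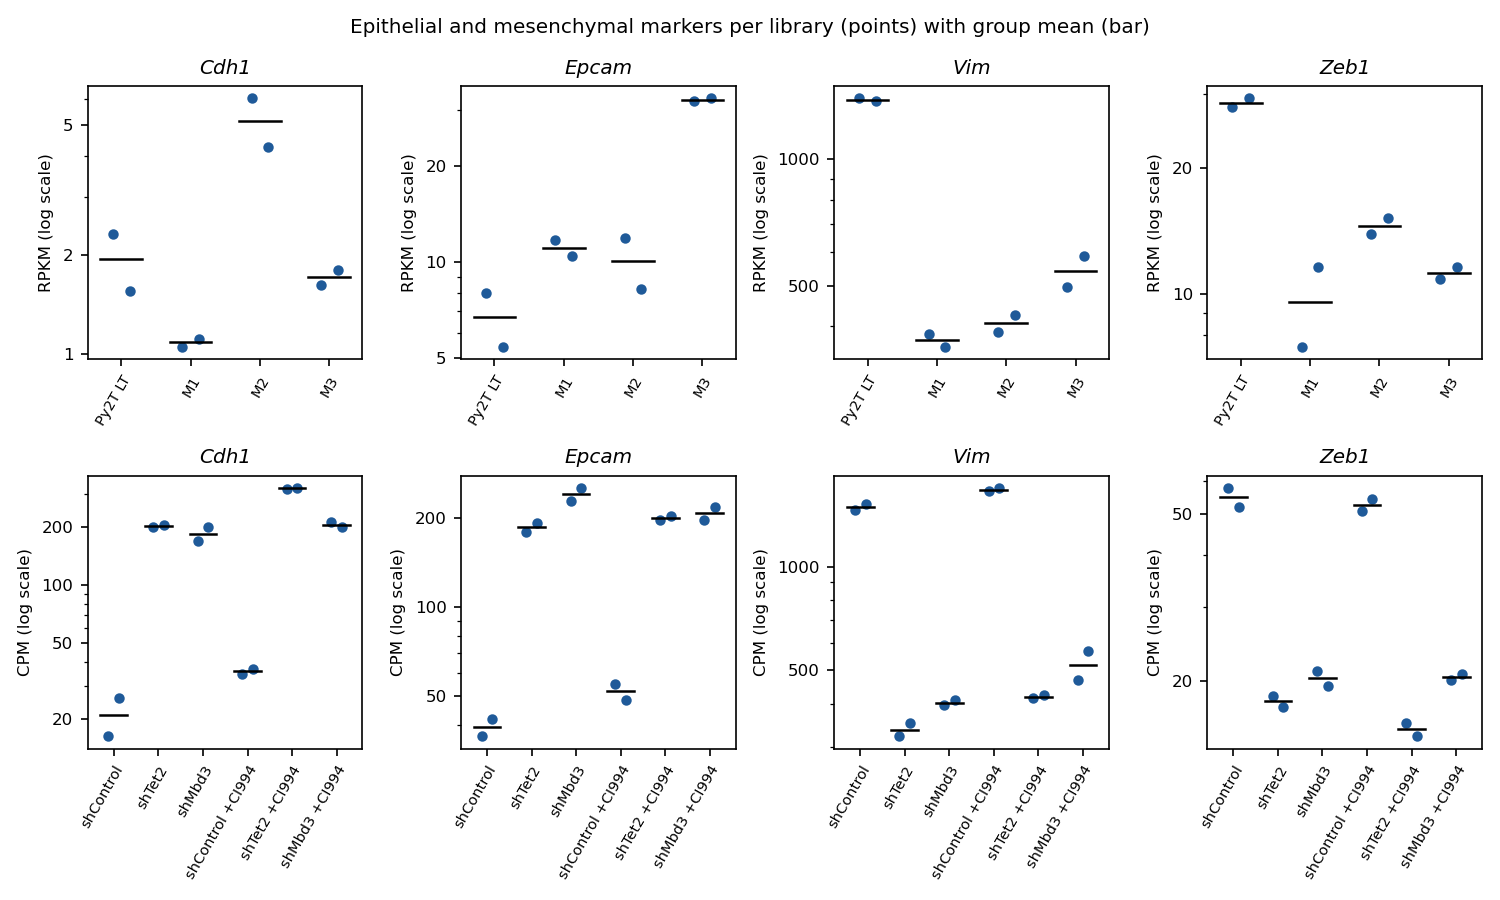
Levels of epithelial and mesenchymal marker genes (vertical axes, RPKM or CPM as marked, log scale) in each library (points), with the mean of each group (bars). Cdh1 is 186 to 320 CPM on average in the 4 knockdown groups and 35.6 in shControl with CI994.

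The combination of knockdown and CI994 was compared with untreated shControl to give the joint change. With shTet2 and CI994, Epha1 rose from 2.54 ± 0.55 to 159 ± 4.2 CPM (SD, n = 2 each), Krt14 from 2.40 ± 2.0 to 62.0 ± 13 and Cdh1 by 3.89 ± 0.16 (log2, SE), while Il1rl1 fell from 117 ± 2.5 to 0.826 ± 0.033 and Vim changed by -1.87 ± 0.10. With shMbd3 and CI994, Ret rose from 2.03 ± 0.30 to 162 ± 9.0, Krt14 to 93.1 ± 21 and Cdh1 by 3.23 ± 0.16, while Gpnmb fell from 144 ± 52 to 1.03 ± 0.57 and Vim changed by -1.60 ± 0.10. Of 34 epithelial genes 33 rose and 0 fell with shTet2 and CI994 (33 and 0 adjusted over the list alone; camera adjusted p = 3.45e-14, and adjusted p = 0.250 with an estimated correlation). With shMbd3 and CI994 28 rose and 0 fell (30 and 0 adjusted over the list alone; camera adjusted p = 1.49e-13, and adjusted p = 0.381 with an estimated correlation). For shTet2 with CI994 camera also called MHC class I presentation (adjusted p = 0.00513), p53 targets (adjusted p = 0.00287), the stress list (adjusted p = 0.0392), cholesterol synthesis (adjusted p = 0.0353), glycolysis and hypoxia (adjusted p = 0.00513) and ribosomal proteins (adjusted p = 0.00513) higher, and EMT transcription factors (adjusted p = 0.00287) lower. These calls did not hold with an estimated correlation (adjusted p = 0.246 or more), and the calls of the stress list and cholesterol synthesis were also lost without 1 library. The stress call was lost with the GC trend removed too (adjusted p = 0.120, and 0.153 with the block as well). For shMbd3 with CI994 camera also called MHC class I presentation (adjusted p = 0.000133) and p53 targets (adjusted p = 0.0238) higher. No such call held with an estimated correlation (adjusted p = 0.381 or more), and the call of p53 targets was also lost without 1 library (adjusted p = 0.133). The counts of genes were 7530 (3786 higher, 3744 lower) and 7050 (3554 and 3496). Without the library labelled M3_shControl replicate 1 they were 6961 and 6687, without shTet2_CI994 replicate 1 or 2 the first was 4798 and 4989, and without shMbd3_CI994 replicate 2 the second was 4045. With only the groups compared they were 1782 and 1625.

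**Figure D5:**
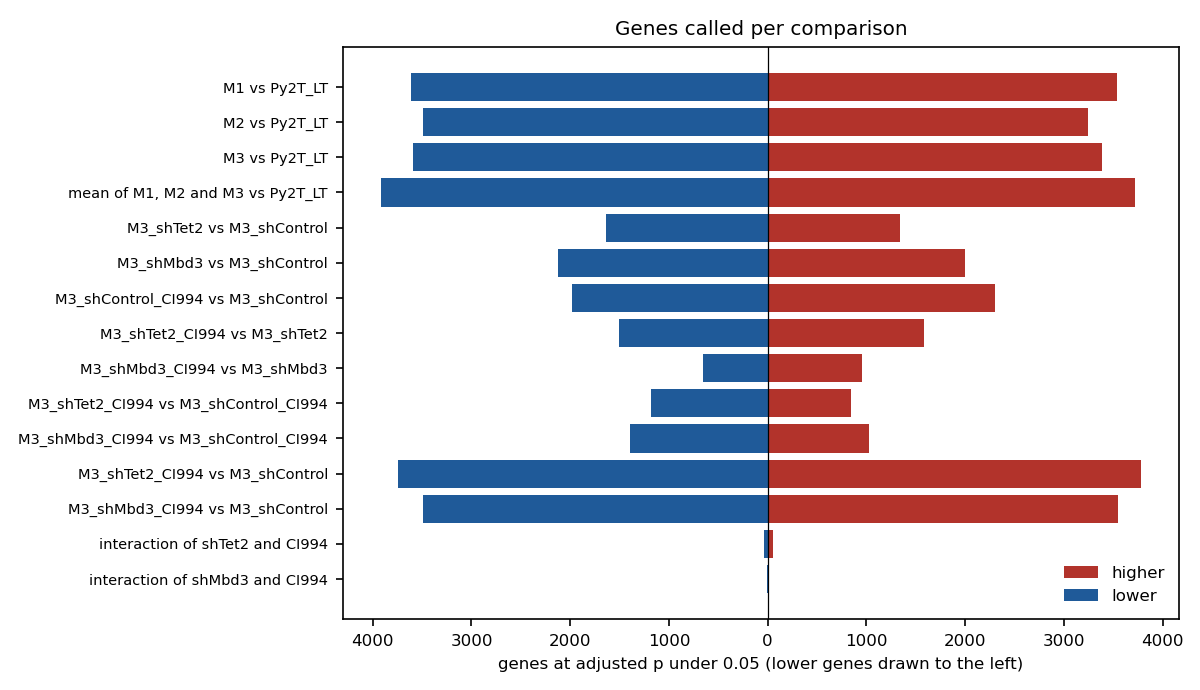
Number of genes at a limma adjusted p under 0.05 (horizontal axis), higher to the right and lower to the left, in each comparison with a direction (groups of bars). The largest count is 7638, for the mean of the clones against Py2T LT.

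The interaction asks whether a knockdown changed expression differently with CI994 than without it. For shTet2, Scn3a was 0.0236 and 18.3 CPM on average in shTet2 cells without and with CI994, an interaction of 2.79 ± 0.28 (log2, SE; n = 2 each; adjusted p = 0.0111), and Sema4f gave 2.82 ± 0.34 (adjusted p = 0.0163). The glycolytic gene Pfkp gave -2.04 ± 0.21 (adjusted p = 0.0111), Mmp13 -2.08 ± 0.31 (adjusted p = 0.0227) and the laminin gene Lama3 -1.99 ± 0.29 (adjusted p = 0.0227). In all, 88 genes passed, 53 positive and 35 negative, against 36 by edgeR on the recovered reads. Cdh1 gave -0.18 ± 0.22 (adjusted p = 0.842), which was 0.08 without the library labelled M3_shControl replicate 1 and passed at -0.44 without replicate 2 (adjusted p = 0.0177). The calls of Scn3a, Sema4f, Pfkp, Mmp13 and Lama3 were all lost without shTet2 replicate 1 (adjusted p = 0.0828 to 0.0935), shControl_CI994 replicate 1 (0.0715 to 0.105) or shTet2_CI994 replicate 1 (0.0618 to 0.117), and with only the groups compared (0.101 to 0.127). By edgeR Scn3a was 4.80 (adjusted p = 0.182) and Sema4f 3.30 (adjusted p = 0.0615), and by DESeq2 Scn3a was 5.05 (adjusted p = 0.0813). For shMbd3, 5 genes passed. Itga8 gave 2.47 ± 0.27 (adjusted p = 0.0288), the secreted protein genes Edil3 1.92 ± 0.23 (adjusted p = 0.0369) and Tafa5 1.91 ± 0.24 (adjusted p = 0.0475). Ces1f and U90926, chosen after their values were seen, gave -2.20 ± 0.21 and -2.49 ± 0.23 (adjusted p = 0.0104 each).

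The interaction counts rested on single libraries. Without the library labelled M3_shControl replicate 1 they were 775 (374 positive, 401 negative) for shTet2 and 93 (49 and 44) for shMbd3, and without M3_shControl replicate 2 they were 4802 and 6254. The shTet2 count was 0 to 15 without any single one of the other 6 libraries it uses, and the shMbd3 count 0 or 1 without any single one of its other 6. Tafa5 and Ces1f had 0 CPM on average in shMbd3 with and without CI994, so their interactions are the CI994 change in shControl cells with its sign turned, and their size depends on the pseudocount. Itga8 was 33.2 and 2.57 CPM on average in shControl without and with CI994 and 0.673 and 0.0731 in shMbd3. Its interaction was 1.53 at a pseudocount of 0.1 (adjusted p = 0.284), 0.66 by edgeR (adjusted p = 0.786) and 0.59 by DESeq2 (adjusted p = 0.813). None of the 5 genes passed by edgeR or at that pseudocount, and Tafa5 did not pass by DESeq2 either (adjusted p = 0.681). In counts of reads the sign of U90926 was positive, at 2.16 by edgeR and 1.72 by DESeq2. The 12 M3 shRNA libraries held 4 genes each of the cyclin-dependent kinase inhibitor and haematopoietic lists and 3 each of the germline and endothelial lists, too few for a list test. The interaction of Cdh1 with shMbd3 was -0.60 ± 0.22 (log2, SE; adjusted p = 0.331), and passed without M3_shControl replicate 2 (-0.86).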

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

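The tests of the library labelled M3_shControl replicate 1, of p53 targets, of reads of Cdkn2a and Cdkn2b, and of chromosome 1 within CI994 against that library were chosen only after the result was seen. Among the clones M1, M2 and M3, 3009 genes passed a test of any difference. An effect of shTet2 that differed with and without CI994 passed in 88 genes, with interactions of 2.79 for Scn3a, 2.82 for Sema4f, -2.08 for Mmp13, -2.04 for Pfkp and -1.99 for Lama3. The calls of all 5 genes were lost without shTet2 replicate 1 (adjusted p = 0.0828 to 0.0935), among other single libraries. In lists, the shTet2 interaction was negative for cholesterol synthesis (camera adjusted p = 7.52e-08), epithelial genes (7.35e-07), glycolysis and hypoxia (1.54e-15), proliferation (0.0372) and ribosomal proteins (4.73e-07), and positive for interferon-stimulated genes (7.72e-07). With an estimated correlation these were adjusted p = 0.319, 0.366, 0.0700, 0.238, 0.366 and 0.0700. The proliferation call was lost without M3_shControl replicate 2 (adjusted p = 0.484), shTet2 replicate 1 (0.0605), shControl_CI994 replicate 1 (0.0677) or shTet2_CI994 replicate 2 (0.0662), and with only the groups compared (0.0523). For shMbd3 and CI994 5 genes passed: Itga8 at 2.47, Edil3 at 1.92, Tafa5 at 1.91, Ces1f at -2.20 and U90926 at -2.49. In lists, that interaction was positive for EMT transcription factors (camera adjusted p = 0.00352) and negative for cholesterol synthesis (1.61e-05), epithelial genes (2.60e-06), glycolysis and hypoxia (1.19e-07), the stress response (0.000324) and ribosomal proteins (6.41e-06). With an estimated correlation these were adjusted p = 0.316, 0.415, 0.415, 0.316, 0.349 and 0.505. Both interactions subtract the same CI994 change in shControl cells, which includes the library labelled M3_shControl replicate 1. Lists called in both interactions are therefore not independent results. The EMT factor call was lost without M3_shControl replicate 2 (adjusted p = 0.107).

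The library labelled M3_shControl replicate 1 stood apart from its replicate. Across genes the pair correlated at r = 0.964, against 0.995 or more for the other CPM pairs, and its difference from replicate 2 per gene exceeded counting error by a chi-square per degree of freedom of 134 against 7.44 to 10.5. A GC bias is a candidate explanation for the broad difference, since the median difference changed by -1.77 from the lowest to the highest GC decile, more than in any other pair. A mislabelled shMbd3 library is argued against: after GC correction the difference correlated at -0.0127 across genes with the shMbd3 effect measured within CI994. The low Mbd3 value stays open, since Mbd3 was the lowest of 46 genes of like GC content (log2 difference -3.39 against a median of -1.78), and no biological explanation of it was tested.

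Blocks of neighbouring genes differed between the clones and Py2T LT. From Cpm to Dyrk2 on chromosome 10, 8 consecutive tested genes, chosen for their low values, had a median log2 difference of -3.98. GC content is argued against by a median of -3.95 with the GC trend removed, and induction of p53 targets in Py2T LT by the other 18 targets of the list, whose median was 0.359 with 9 higher and 5 lower in the clones. A difference in gene copies was not tested, because the 8 genes were chosen by their values and no DNA was measured. Silencing of Cdkn2a and Cdkn2b that CI994 relieves is argued against by 0 reads of either gene in the 6 CI994 libraries, and a loss of both genes in the clones was not tested.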

How the results depend on the processing

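Alternatives named as chosen after seeing the data are the pseudocounts and the GC trend removed. EdgeR, the design's main test, was run as an alternative on the recovered reads of the CPM libraries. With 1 library left out its partner is assumed to vary like the other groups. Without M3_shControl replicate 2 that partner is the library labelled M3_shControl replicate 1, with its GC trend. The range of genes passing was 5726–7755 for M1, 5003–5430 for M2, 5468–5846 for M3, 5999–8389 for their mean and 1017–5981 among clones. For shTet2 it was 1338–8089, shMbd3 1560–8696, CI994 1118–8973, CI994 in shTet2 904–1362 and in shMbd3 448–568. Within CI994 it was 984–1060 for shTet2 and 1260–1306 for shMbd3, for the combinations 4798–9862 and 4045–9640, for the interactions 0–4802 and 0–6254, and for list calls 80–94. Counts of 0 without one library came from limma.

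With only the groups compared, fewer samples set the spread, and the untreated shControl pair enters it only where that pair is compared. The counts were 330 for shTet2, 306 for shMbd3, 0 for CI994 (2625 unadjusted), 7350 for CI994 in shTet2, 4637 in shMbd3, 5230 and 4708 for the knockdowns within CI994, 1782 and 1625 for the combinations, and 0 for both interactions (1050 and 995 unadjusted, limma). Against the main fit they fell in every CPM comparison that uses untreated shControl and rose in all other CPM comparisons. With the GC trend removed the counts were 4875 for shTet2, 3309 for CI994 in shMbd3, 3721 and 4436 within CI994, and 535 and 114 for the interactions. With the block as well they were 5849, 6358, 5241, 4450, 4687 and 5454 for shTet2, shMbd3, CI994 in shTet2, CI994 in shMbd3 and the knockdowns within CI994, and 1129 and 570 for the interactions. The replicate block alone gave 2440 for CI994 in shMbd3 and 165 and 30 for the interactions. Replicate numbers were not taken as pairs, since no label ties a number to an experiment. The 15 correlations between CPM groups of the replicate differences were all positive, from 0.0954 to 0.523 with a median of 0.359. Among the RPKM groups they ranged from -0.122 to 0.128. An effect shared by libraries of the same number is therefore not excluded in the CPM set. The shTet2 interaction was 49 at a pseudocount of 0.1, 36 by edgeR and 267 by DESeq2. The shMbd3 interaction was 9 with RLE factors, 36 without a filter, 0 at a pseudocount of 0.1 (1510 unadjusted, limma), 42 at 1, 0 by edgeR (1490 unadjusted) and 115 by DESeq2. List calls with an estimated correlation were 0 (34 unadjusted). The cause was not tested for these counts.

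These values turned direction in some setting, given as ranges over leaving out 1 library. Mbd3 in shMbd3 ranged from -1.41 (without the library labelled M3_shControl replicate 1) to 1.99 (without replicate 2) and was -0.50 with the GC trend removed, -0.50 with the block too, -0.54 by edgeR and -0.54 by DESeq2. Mbd3 in shTet2 ranged from -0.0226 to 3.37, Zeb1 with CI994 from -0.227 to 0.0411 (0.11 with the GC trend removed, 0.11 with the block too), and Cdh1 in the shTet2 interaction from -0.441 to 0.0798. U90926 was 2.16 by edgeR and 1.72 by DESeq2. In the clones Cdh1 ranged from -0.0954 to 0.357 and Hdac8 from -0.00493 to 0.0781. The mesenchymal list in shMbd3 turned with the GC trend removed (adjusted p = 0.626), with the block too (0.614) and without the library labelled M3_shControl replicate 1 (0.706), with a range up to 0.982. In shTet2 within CI994 it turned without shControl_CI994 replicate 1 (0.865) or shTet2_CI994 replicate 1 (0.885), and its lowest was 0.764. Of 324 named genes and lists, the call stayed the same in 323 with RLE factors, 319 with library size only, 320 with the block, 317 without a filter and 306 with the GC trend removed. With only the groups compared 54 were lost, 1 was gained and 220 stayed the same, and with an estimated correlation 90 list calls were lost and 20 stayed. Over all fits without 1 library 103 were lost, 8 gained and 9 turned, against 1486 that stayed the same. DESeq2 was not run on the RPKM libraries, which give no counts, and their unknown depth limits what a 0 there means.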

Other observations

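The tests of chromosome 1 genes along the chromosome and after GC correction were set out before their results, and that of the untreated shControl library only after the result was seen. Genes of chromosome 1 and the X-linked RNA Xist, both chosen after their values were seen, were lower in the shTet2 libraries. Xist measured 1536 and 1162 CPM in the libraries labelled shControl, 109 and 65.1 in shTet2, and 469 and 514 in shMbd3. With CI994 it measured 813 and 856 CPM in shControl, 85.3 and 75.8 in shTet2, and 596 and 489 in shMbd3. Against shControl_CI994, Xist changed by -3.38 ± 0.24 (log2, SE; n = 2 each; adjusted p = 3.33e-05) with shTet2. The 750 tested genes of chromosome 1 had a median log2 difference of -0.379 for shTet2 against shControl and -0.414 within CI994. Chromosome 1 was not alone within CI994, where other chromosomes with more or fewer genes had medians of -0.222 for chromosome 18, -0.201 for 11, -0.164 for 13 and 0.194 for 17. Chromosome 1 was also lower with shMbd3, at a median of -0.272 against shControl. Within CI994 68.8% of its genes were below 0 with shMbd3, and its bins ranged from -0.246 to -0.153.

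For chromosome 1, GC content is argued against by a median of -0.360 within CI994 with the GC trend removed. The library labelled M3_shControl replicate 1 does not enter the group means compared within CI994, where the median was -0.414. Fewer copies of chromosome 1 in the shTet2 cells is a candidate explanation that its test could not decide. The test asked for every bin of the chromosome at a median of -0.2 or below, which was not met. Of 10 bins 8 were, with medians from -0.525 to a highest bin of -0.125. Fewer copies cannot be told apart from an effect of the Tet2 knockdown or from a difference in the shControl cells, which both knockdowns were compared with, because no DNA was measured.

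Of the haematopoietic markers, too few for a list test, 2 of 4 tested genes passed upward with CI994 in shControl cells and 0 downward. Lyz2 rose from 0.185 ± 0.13 to 3.41 ± 0.27 CPM (SD, n = 2 each) and Cd68 from 1.56 ± 0.71 to 6.76 ± 0.11, with adjusted p of 0.000492 and 0.000986 (limma). Both calls were lost with only the groups compared (adjusted p = 0.0593 and 0.0972).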
